A study of Mus musculus with 12 samples.

How the data were processed

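Gene expression was measured on 12 Affymetrix whole-transcript arrays, 1 per RNA sample, in mouse induced pluripotent stem (iPS) cells at passage 4. Per the labels, lentiviruses carrying Oct4, Sox2, Klf4 and cMyc had reprogrammed 4 kinds of somatic cell: granulocytes of the bone marrow, B cells of the spleen, fibroblasts of the tail tip and precursors of skeletal muscle. Each origin has 3 arrays, called biological replicates in the labels, which do not say whether the replicates came from separate animals or separate clones. If the 3 arrays of an origin share a clone, a difference between origins cannot be told apart from 1 between clones. The cells grew on irradiated embryonic fibroblast feeders in medium with LIF, and a preplating step removed feeder cells before total RNA was isolated.

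The authors deposited 1 log2 intensity per probe set and array, made with Affymetrix Expression Console, version not stated, per the submitters' processing notes. How the arrays were normalized and their background corrected is not given in the sources used here. Intensities carry no counts, so the number of arrays is what limits the precision. All 12 columns and all 35556 probe sets entered the fit. Of these, 21789 have 1 gene symbol, 1621 have several and 12146 have none, and control probe sets are not marked. A probe set with several symbols counts in the totals but is never named. A gene is represented by its probe set of the highest mean over the 12 arrays, which leaves 19938 genes, of which 999 have 2 or more probe sets. Symbols were checked through Entrez identifiers for 21698 probe sets, and 0 changed. Chromosomes and the order of genes come from a RefSeq gene table of mouse assembly GRCm38.p6. The annotation of the arrays names no assembly, so no coordinates are given.

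Differences were computed in R 4.3.3 with limma 3.58.1 and the package data.table, version 1.17.8. The linear model had 1 coefficient per origin, and limma's empirical Bayes step gave 3.253 prior and 11.25 total degrees of freedom. The moderated F test asked which probe sets differ among the 4 origins. Contrasts compared each origin with the unweighted mean of the other 3, the granulocyte and B cell origins with the fibroblast and muscle precursor origins (blood against non-blood), and each pair of origins. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. A rise, fall or change of a gene means such a call. The p-values measure the spread between these samples only.

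Similarity was the mean Pearson correlation of pairs of arrays of the same origin less that of pairs of different origins, after each probe set's mean over the 12 arrays was subtracted. Its one-sided exact permutation test ran over all 15400 partitions of the arrays into 4 sets of 3.

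The comparisons, the rule for naming genes, the gene lists and all but 1 of the alternative settings were fixed before the data were examined. For each contrast of 1 origin, the rule names the 10 highest and 10 lowest log2 differences among called genes whose 3 arrays all lie on 1 side of the other 9. For blood against non-blood and for each pair it names the 5 highest and 5 lowest without overlap of the arrays compared, and for the F test the 10 lowest p. It further names up to 4 members of each list by p, and in any case Pou5f1, Sox2, Klf4, Myc, Nanog, Meg3, Rian, Dlk1, Itgb1, Cxcr4, Lyz1, Lyz2, Ly6g, Csf3r, Xist and the Y-linked genes. Other named genes are said to be chosen after their values were seen.

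The 34 gene lists hold 525 genes, of which 473 matched a probe set, and the unmatched ones were not analysed here. They cover pluripotency, lineage markers of blood, mesenchyme, skin and the early embryo, imprinted, germline and sex-linked genes, and pathways of metabolism, stress and the cell cycle. A list needed 3 matched genes, so that a list of genes of the 2-cell embryo and a list for X inactivation could not be tested. The other lists were tested with limma's camera at a preset correlation of 0.01 on the 4 contrasts of 1 origin and on blood against non-blood, 160 tests adjusted together. Camera compares a list with all other genes. It was repeated with a correlation estimated from the residuals, and with fry, which asks whether the genes of a list move 1 way on balance. Members that rose or fell are counted over all probe sets and adjusted over the list alone.

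The alternatives were quantile normalization of the deposited values, centring of each array on its median, removal of probe sets below the median intensity, probe sets with 1 symbol only, a trended robust prior, array quality weights, the replicate number as a replicate block, each array left out in turn, an added 2-fold threshold, pairs fitted on their own 6 arrays, and, for the similarity, Spearman correlation and the most variable probe sets alone. A fit without the genes of chromosome 11 was chosen after seeing the data. Up to 100 splits of the arrays were refitted for each count of calls.

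Chromosomes were compared with Fisher's exact test, adjusted over all contrasts and chromosomes. For shifts along a chromosome, the 9950 genes above the median intensity were ordered and taken in blocks of 60 neighbours. The shift of a block in an array is its median difference from the mean of the 6 blood-origin arrays, less the median of all such genes.

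The code was tested on simulated data with the real probe sets. In the contrast of fibroblast-derived arrays, 44% of 50 changes of 0.5 on the log2 scale were recovered, 96% of changes of 1, 98% of changes of 2 and 88% of changes of -1, with 10 false calls among 35556 probe sets. Simulations without any change gave 0 to 2 calls per comparison. With 1 list shifted, the 160 list tests gave 5 calls, all in that list.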

Results

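Genome-wide expression was compared among passage 4 iPS cells of 4 cells of origin, with 3 arrays each. The series asks how early-passage iPS cells made from different somatic cells differ. The medians of the 12 arrays lay between 5.825 and 5.931 on the log2 scale, and the spread of intensities (SD over all 35556 probe sets) was 2.163 to 2.198 in the 6 arrays of granulocyte or B cell origin and 2.217 to 2.28 in the 6 arrays of fibroblast or muscle precursor origin.

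All 4 origins carried the core transcripts of pluripotency at high and similar levels. Mean log2 intensities over the origins were 10.7 to 11.1 for Pou5f1, 10.8 to 11.1 for Sox2, 11.0 to 11.2 for Nanog and 9.51 to 9.73 for Klf4, and in limma none of these differed between 1 origin and the other 3 at a Benjamini-Hochberg adjusted p under 0.05. The nearest to a call were Sox2 and Pou5f1 in granulocyte-derived cells (log2 differences -0.21 and -0.29, adjusted p = 0.0617 and 0.0626). Sox2 fell by 0.19 in blood-derived against non-blood-derived cells (SE 0.0512, adjusted p = 0.0181), a call lost under quantile normalization. Myc was the exception among the reprogramming factors, at 7.01 in fibroblast-derived cells and at 6.20 to 6.34 in the others. For Pou5f1, Sox2, Klf4 and Myc, transcripts of the lentiviral copies were not told apart from those of the cells' own genes. Surface and lineage genes of the starting cells, namely Itgb1, Cxcr4, Lyz1, Lyz2, Ly6g and Csf3r, passed the threshold in none of the 5 contrasts of 1 origin or of blood origins. Ly6g (3.44 to 3.55) and Lyz2 (3.91 to 4.24) lay below the lower quartile of the arrays (4.355 to 4.506). Csf3r (4.40 to 4.67) and Lyz1 (4.48 to 4.78) lay near it, so that a missing call says little for these 4. Itgb1 was high in all 4 origins (9.63 to 9.70).

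Arrays of the same origin resembled each other more than arrays of different origins. The mean correlation of deviations was 0.2987 within origins and -0.1708 between them, a difference of 0.4694 (one-sided exact permutation test, p = 6.494e-05, the smallest that the partitions can give). Without centring, the mean correlation of pairs was 0.9904 within and 0.9844 between origins. Granulocyte-derived arrays (0.9925), B cell-derived arrays (0.9931) and muscle precursor-derived arrays (0.9912) were closer to their own group than fibroblast-derived arrays (0.9849). For 10 of the 12 arrays the nearest array was of the same origin. The exceptions were fibroblast-derived array 1, nearest to B cell-derived array 3 (0.9908), and fibroblast-derived array 3, nearest to muscle precursor-derived array 3 (0.9893). The first principal component held 38.8% of the variance and the second held 15%.

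**Figure D1:**
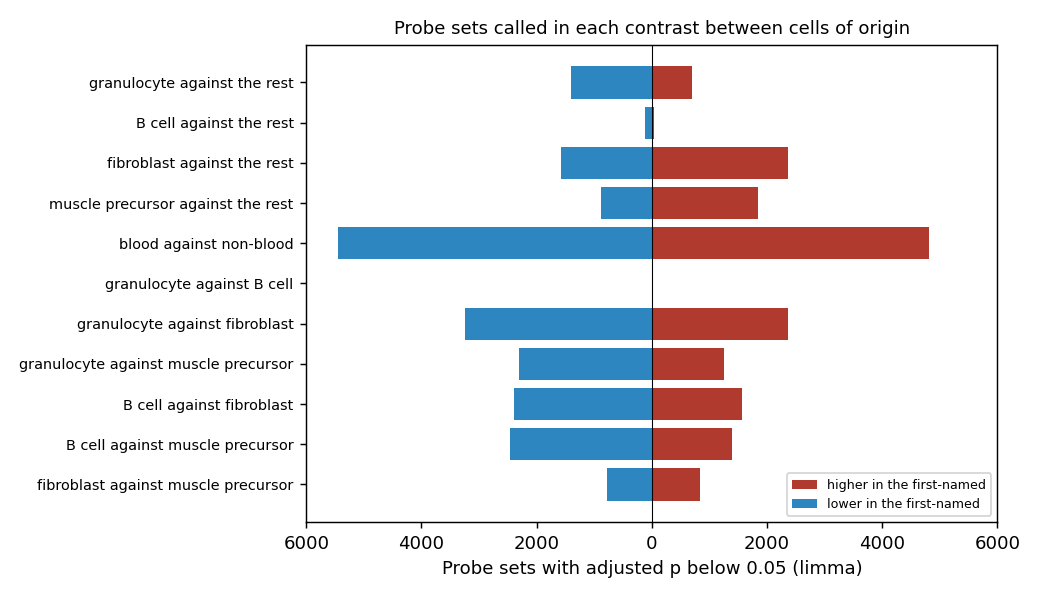
Number of probe sets called at an adjusted p under 0.05 in each contrast, as bars for higher and lower in the group named first. Blood against non-blood has 10266 calls and granulocyte-derived against B cell-derived has 0.

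The F test asks which transcripts differ among all 4 origins. Decorin (Dcn), a proteoglycan made by fibroblasts, had the lowest p of the F test, with means 7.85-fold apart between the highest and lowest origin (adjusted p = 5.83e-07, 3 arrays per origin). The X-linked testis gene Usp26 followed (10.9-fold, adjusted p = 1.78e-06). Tgm1, a transglutaminase of skin, and Laptm5, a lysosomal protein of blood cells, differed by 1.13 and 1.57 on the log2 scale (both adjusted p = 4.43e-05). The rest of the 10 lowest were the potassium channel gene Kcnma1, Ddx60, the mannose enzyme gene Mpi, the X-linked Nxf3 and Efhc2, and the meiotic gene Stra8, with ranges of 1.38 to 3.41 and adjusted p of 4.43e-05 to 5.69e-05. The lowest means of Ddx60 (4.10) and Nxf3 (3.81) lay below the lower quartile of their arrays, so that these ranges depend on the background. A second probe set of Kcnma1 differed by 0.23 between fibroblast-derived and the other cells (adjusted p = 0.117). In total 7122 probe sets differed, or 20% of those tested, among them 4338 genes, and 870 had a range of at least 2-fold. The count was 4325 and 4618 without granulocyte-derived array 1 or 2, 4275 and 4361 without B cell-derived array 1 or 2, and 4537 and 4523 without muscle precursor-derived array 1 or 3.

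Granulocyte-derived cells against the other 3 origins asks what sets these cells apart at passage 4. Meg3, a maternally expressed non-coding RNA of the Dlk1-Dio3 imprinted cluster, was 1.93-fold higher (log2 difference 0.95, SE 0.112, limma with Benjamini-Hochberg adjustment, adjusted p = 0.00278, 3 arrays against 9). Its mean was 8.74, against 7.58 to 8.17 in the other origins. Igf2, a paternally expressed growth factor, rose by 0.87 (SE 0.0778, adjusted p = 0.000876). The other genes at the top were the ephrin gene Efna3 (1.77-fold), the epithelial surface gene Plet1 (1.71-fold), Capn6 (1.70-fold), the adhesion gene Mcam (1.69-fold), Lcat (1.68-fold), the keratin gene Krt18 (1.67-fold), Tuft1 (1.66-fold) and Dcxr (1.64-fold), with adjusted p of 0.00232 to 0.0221. Lower transcripts included those of the surface enzyme gene Enpp3 (2.30-fold, adjusted p = 0.00138), the transferrin receptor Tfrc (2.21-fold, adjusted p = 0.000618), the uridine phosphorylase Upp1 (2.15-fold, adjusted p = 0.0006) and the phospholipase Pla2g1b (2.12-fold, adjusted p = 0.000568). Zic2 (2.06-fold), the fatty acid synthesis gene Acaca (1.92-fold), the interferon-inducible Ifitm3 (1.88-fold), the hypoxia gene Bnip3 (1.85-fold) and the microRNA precursors Mir363 (2.04-fold) and Mir302b (1.87-fold) completed the list, with adjusted p of 0.000682 to 0.0145. With granulocyte-derived array 1, 2 or 3 left out, Lcat and Mir363 lost their calls (adjusted p of 0.0555 to 0.095). Tuft1 and Mir302b lost theirs without array 1 or 2 (0.0539 to 0.073).

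Genes of pluripotency, hypoxia and sterol synthesis were lower in granulocyte-derived cells, and p53 targets were higher. Of 26 pluripotency genes 0 rose, 9 fell and 17 did not pass, and 17 fell when adjusted over the list alone, with Tdgf1 (-0.65), Prdm14 (-0.55) and Dppa2 (-0.70) among them (camera, adjusted p = 1.68e-09; adjusted p = 0.29 with an estimated correlation). Of 16 glycolysis and hypoxia genes 9 fell, 7 did not pass and 12 fell adjusted over the list alone, such as Ndrg1 (-0.77) and Egln3 (-0.75; adjusted p = 2.16e-07, and adjusted p = 0.117 with an estimated correlation). Of 12 cholesterol synthesis genes 8 fell, 4 did not pass and 11 fell adjusted over the list alone, such as Fdps (-0.46) and Nsdhl (-0.53; adjusted p = 6.34e-08, and adjusted p = 0.259 with an estimated correlation). Of 15 p53 targets 7 rose, 0 fell and 8 did not pass, while 9 rose and 1 fell adjusted over the list alone. Phlda3 and Perp rose by 0.66 and 0.63 (adjusted p = 7.31e-07 for the list, and adjusted p = 0.0834 with an estimated correlation). The ATF4 and ER stress list rose through Cth (0.65) and 2 more of its 13 genes, 5 with 1 fall adjusted over the list alone (adjusted p = 0.014; adjusted p = 0.421 with an estimated correlation).

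A further 7 lists were called in granulocyte-derived cells, each with 1 to 3 members passing. In the formative and primed epiblast list 3 of 11 genes fell, both over all genes and adjusted over the list alone, with Lef1 and Otx2 each at -0.75 (adjusted p = 0.0318; adjusted p = 0.437 with an estimated correlation). Dnmt3b, at -0.56, was the 1 gene of 8 that fell in the DNA methylation machinery list, against 4 adjusted over the list alone (adjusted p = 0.00692; adjusted p = 0.368 with an estimated correlation). In the Dlk1-Dio3 imprinted cluster list Meg3 and Rian (0.62, adjusted p = 0.0108) rose out of 5 genes, the same count adjusted over the list alone, and Dlk1 did not pass (adjusted p = 0.0374; adjusted p = 0.368 with an estimated correlation). Rian lay below the lower quartile of the arrays in B cell-derived (4.29) and muscle precursor-derived cells (4.08), so that its difference depends on the background. In the extracellular matrix list 3 of 28 genes fell, 5 adjusted over the list alone, led by Dcn (-1.06, adjusted p = 0.00233 for the list; adjusted p = 0.406 with an estimated correlation). The Dcn difference comes from the fibroblast-derived arrays in the comparison group, as its mean was 5.76 here, 5.83 in B cell-derived and 5.90 in muscle precursor-derived cells. Laptm5 (0.46), low in fibroblast-derived cells alone (7.71 against 9.21 to 9.28), was the 1 pan-blood gene of 19 that rose by either adjustment (adjusted p = 0.0398 for the list; adjusted p = 0.464 with an estimated correlation). Myc (-0.36, adjusted p = 0.0354; mean 6.20, against 6.33 in B cell-derived and 6.34 in muscle precursor-derived cells) was the 1 reprogramming factor of 4 that fell, 3 adjusted over the list alone, and Ndufa9 and Ndufv1 (-0.34 and -0.41) fell out of 19 oxidative phosphorylation genes, 4 adjusted over the list alone (adjusted p = 0.0186 and 0.0162; adjusted p = 0.437 with an estimated correlation for both). The granulocyte list itself was not called (adjusted p = 0.101). Of its 28 genes 21 were higher, but the 1 that passed, Anxa1, fell by 0.73 (adjusted p = 0.00882). Under quantile normalization the calls of the Dlk1-Dio3, DNA methylation machinery, pan-blood, reprogramming factor and oxidative phosphorylation lists were lost. Without dim probe sets those of the formative, matrix, Dlk1-Dio3, pan-blood, reprogramming factor and oxidative phosphorylation lists were lost. The pan-blood call was also lost with fry and without chromosome 11 genes, a fit chosen after seeing the data, and the Dlk1-Dio3 call under array quality weights. Calls also ended without granulocyte-derived array 1 for Otx2 (0.054), Anxa1 (0.0682) and the oxidative phosphorylation list (0.0673), and without fibroblast-derived array 2 for the formative list (0.0772). Dnmt3b lost its call without granulocyte-derived array 1 or 2, Rian, Laptm5 and Ndufa9 without any 1 of the granulocyte-derived arrays, Ndufv1 without 4 of the arrays in turn and Myc without 8 (0.0502 to 0.2). The pan-blood list was lost without granulocyte-derived array 1, fibroblast-derived array 3 or muscle precursor-derived array 2, and the Dlk1-Dio3 list without any 1 of the fibroblast-derived arrays or muscle precursor-derived array 2 (0.051 to 0.065).

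In all, 695 probe sets were higher and 1405 lower in granulocyte-derived cells (2100 calls, 1432 genes), and 46 differed at least 2-fold, 7 higher and 39 lower. The higher share of calls was 33.1%, 44.3% under quantile normalization and 18.8% with array medians centred. Of chromosome 11 genes, Upp1 and Acaca included, 14.1% fell, against 4.35% elsewhere, and the comparison group holds the fibroblast-derived arrays, in which this chromosome is shifted upward by 0.253 to 0.289 against the blood origins. The count of calls was 181, 287 and 441 without granulocyte-derived array 1, 2 or 3, 1169, 1363 and 1092 without B cell-derived array 1, 2 or 3, 1235 without muscle precursor-derived array 3 and 5154 without fibroblast-derived array 1.

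B cell-derived cells against the other 3 origins gave the fewest calls of the 4 contrasts of this kind (158), but not under array quality weights (4059, against 1548 for fibroblast-derived cells). The X-linked Scml2, a polycomb-related gene active in the testis, was 3.95-fold lower (log2 difference -1.98, SE 0.236, limma with Benjamini-Hochberg adjustment, adjusted p = 0.00524, 3 arrays against 9). Usp26 was lower by -1.60 (SE 0.11, adjusted p = 0.000428), and Dazl, an RNA-binding protein gene of germ cells, was 2.02-fold lower (adjusted p = 0.0048). The meiotic genes Meioc (-0.87), Shoc1 (-0.84), Stra8 (-0.83) and Hormad2 (-0.73) fell too, as did the predicted gene Gm5662 (-1.53), the imprinted retrogene Mcts2 (-0.87) and Taf9b (-0.77), with adjusted p of 0.0048 to 0.0366. Gm5662 lay below the lower quartile of the B cell-derived arrays, so that its difference depends on the background. The genes that rose changed less. They were the growth factor gene Pdgfc (1.63-fold, adjusted p = 0.0154), the mesendoderm gene Cer1 (1.59-fold, adjusted p = 0.0384), the serotonin synthesis gene Tph1 (1.51-fold, adjusted p = 0.0259), 2610318N02Rik, Tmem72, Cstdc6, 1700010I14Rik, the amino acid transporter gene Slc38a5, Cacng1 and the myeloid receptor gene Cd300c, the last 7 at 0.44 to 0.57. A second probe set of 2610318N02Rik did not pass (0.56, adjusted p = 0.054). None of these 20 genes was called between B cell-derived and granulocyte-derived cells. Only Usp26 kept its call with each of the 12 arrays left out in turn. Scml2 and Dazl lost theirs without B cell-derived array 1 (adjusted p = 0.0586 and 0.056). Meioc, Shoc1 and Stra8 lost theirs without B cell-derived array 1 or 2 (0.0559 to 0.0771), Mcts2 without B cell-derived array 2 or 3 (0.0732 and 0.0934), and Pdgfc and 2610318N02Rik without any 1 of the B cell-derived arrays (0.0873 to 0.125). The remaining 11 lost theirs without 4 to 10 of the arrays (up to 0.238).

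As a group, all 15 germline genes repressed by DNA methylation were lower in B cell-derived cells, with a median of -0.41. Of these 4 fell, 11 did not pass and 10 fell adjusted over the list alone (adjusted p = 1.98e-10; adjusted p = 0.0834 with an estimated correlation). Dazl led, and Stk31 (-0.69), Sycp1 (-0.65) and Asz1 (-0.69) each had an adjusted p of 0.0486, up to 0.232 with 1 array left out. The B cell list rose, with 21 of 23 genes higher, but 0 passed over all genes and 1 adjusted over the list alone. Blnk (0.27, adjusted p = 0.0723) and Ighm (0.33, adjusted p = 0.0941) came nearest (list adjusted p = 0.0162; adjusted p = 0.464 with an estimated correlation). In the primitive streak and mesoderm list 0 of 11 passed over all genes and 6 rose adjusted over the list alone, with Fgf8 at 0.43 (adjusted p = 0.0532; list adjusted p = 0.00759, and adjusted p = 0.368 with an estimated correlation). Laptm5 (0.52, adjusted p = 0.0331) was the 1 of 19 pan-blood genes that rose by either adjustment, and Dcn (-0.97, adjusted p = 0.00176) the 1 matrix gene of 28 that fell, against 8 falls and 1 rise adjusted over the list alone. Both differences come from the fibroblast-derived arrays, as the means in the other 3 origins were 9.21 to 9.28 for Laptm5 and 5.76 to 5.90 for Dcn. The Laptm5 call was lost without 9 of the arrays in turn (up to 0.21). Those lists had an adjusted p of 0.0255 and 0.0203, and both had adjusted p = 0.437 with an estimated correlation. The mitotic cell cycle (adjusted p = 0.00438), cytosolic ribosomal protein (0.0334) and primitive endoderm (0.0456) lists fell and the granulocyte list rose (0.0456), all 4 with 0 genes passing and adjusted p = 0.437 with an estimated correlation. Adjusted over the list alone, 1 mitotic gene fell, and 1 primitive endoderm gene rose and 4 fell, with 0 ribosomal and 0 granulocyte genes. All of these list calls except the germline and primitive streak lists were lost under quantile normalization, and those of the primitive endoderm, matrix, mitotic and ribosomal lists also without dim probe sets. Without chromosome 11 genes, a fit chosen after seeing the data, the ribosomal and granulocyte list calls and those of Stk31, Sycp1 and Asz1 were lost, the mitotic call was lost with fry, and the primitive endoderm call under array quality weights and with the replicate block. Single arrays also decided the primitive endoderm, granulocyte, ribosomal, matrix and pan-blood lists, whose adjusted p reached 0.112, 0.1, 0.0738, 0.0607 and 0.074 with 1 array left out.

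B cell-derived cells gave 158 calls (41 higher, 117 lower, 93 genes), of which 27 were at least 2-fold, 1 higher and 26 lower. The higher share was 25.9%, and 15.4% with array medians centred. Every array left out moved this count more than 1.5-fold. It was 50, 40 and 47 without granulocyte-derived array 1, 2 or 3, 16, 23 and 33 without B cell-derived array 1, 2 or 3, 4299, 319 and 263 without fibroblast-derived array 1, 2 or 3, and 37, 79 and 55 without muscle precursor-derived array 1, 2 or 3. The count also rose more than 1.5-fold under quantile normalization, with array medians centred, without dim probe sets and with probe sets of 1 symbol. The same held for the trended robust prior, array quality weights and the replicate block. Without chromosome 11 genes, a fit chosen after seeing the data, it fell more than 1.5-fold.

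Fibroblast-derived cells against the other 3 origins gave the most calls of the 4 contrasts of this kind (3941), but the fewest under array quality weights (1548, against 4059 to 4676), and fewer than muscle precursor-derived cells without fibroblast-derived array 3 (2621 and 6130). Dcn was 7.49-fold higher (SE 0.0874 on the log2 scale, limma with Benjamini-Hochberg adjustment, adjusted p = 4.84e-08, 3 arrays against 9), with a mean of 8.74 against 5.76 to 5.90 in the other origins. The X-linked Usp26 (7.97-fold, SE 0.11, adjusted p = 2.26e-07), Scml2 (7.82-fold, SE 0.236, adjusted p = 3.38e-05) and Nxf3 (7.18-fold, SE 0.187, adjusted p = 1.26e-05), all known from the testis, rose as much. Further up were Ccdc152 (3.83-fold), the antiviral helicase gene Ddx60 (3.59-fold), Tcim (3.56-fold), the oocyte gene Nlrp4c (3.52-fold), the X-linked Efhc2 (3.41-fold) and the interferon-inducible GTPase gene Irgm1 (log2 1.76), with adjusted p of 4.79e-06 to 0.000213. Ccdc152, Ddx60 and Nlrp4c in the other 3 origins and Nxf3 in the blood origins lay below the lower quartile of the arrays, so that their folds depend on the background. Laptm5 was 2.89-fold lower (SE 0.0824, adjusted p = 3.91e-06), with 7.71 in fibroblast-derived cells and 9.21 to 9.28 in the other 3 origins, the muscle precursor origin included. The cysteine synthesis gene Cth fell by 1.17, the skin transglutaminase gene Tgm1 by 1.10 and the purine synthesis gene Adssl1 by 1.21 on the log2 scale, with adjusted p of 3.91e-06 to 0.000181. The surface and adhesion genes Plet1 (-1.13), Efna3 (-1.11), Bcam (-1.08) and Mpzl2 (-1.04) and the tooth matrix gene Tuft1 (-0.99) fell as well, with adjusted p of 2.61e-05 to 0.000447. The deubiquitinase gene Usp17ld was lower by -2.37 with a large error (SE 0.566, adjusted p = 0.0218), and its call was lost without fibroblast-derived array 2 or 3 (0.0916 and 0.114) and under array quality weights. The other 19 genes kept their calls in every setting run for them. Myc rose by 0.72 (SE 0.0861, adjusted p = 0.000437), and Xist by 1.37 (SE 0.105, adjusted p = 2.74e-05), to a mean of 5.97 against 4.58 to 4.66 in the other origins.

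Matrix genes rose and p53 targets fell in fibroblast-derived cells. Of 28 fibroblast and extracellular matrix genes 19 rose, 1 fell and 8 did not pass, and 20 rose and 2 fell adjusted over the list alone, with a median of 0.50 (camera, adjusted p = 1.37e-13; adjusted p = 0.0834 with an estimated correlation). Postn (1.27, adjusted p = 4.25e-05), Col6a3 (0.99, adjusted p = 1.42e-05) and Thbs2 (0.95, adjusted p = 2.59e-05) followed Dcn. Of the 3 members with a mean above 10, Vim (0.66, adjusted p = 0.00026) and Col1a1 (0.36, adjusted p = 0.0377) rose and Fn1 fell (-0.26, adjusted p = 0.0321). Of 15 p53 targets 1 rose, 9 fell and 5 did not pass, with 11 falls and 1 rise adjusted over the list alone, such as Perp (-0.93), Phlda3 (-0.67), Mdm2 (-0.68) and Pmaip1 (-0.62; adjusted p = 9.05e-07, and adjusted p = 0.0834 with an estimated correlation). The Y-linked list rose through Zfy1 (adjusted p = 0.000632) and Kdm5d (0.66) out of 5 genes, 4 adjusted over the list alone (adjusted p = 0.00217; adjusted p = 0.115 with an estimated correlation). In the other origins the means of both genes lay below the lower quartile of the arrays, so that the differences depend on the background. The interferon response list rose through Oasl2 (1.26, adjusted p = 3.12e-05) and Ifitm3 (1.05, adjusted p = 2.59e-05), while Usp18 fell (-0.50) out of 11 genes, 3 rises and 1 fall adjusted over the list alone (adjusted p = 0.0263; adjusted p = 0.29 with an estimated correlation). That list lost its call without fibroblast-derived array 1 (0.0613), and Usp18 lost its own without array 2 (0.0619).

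Stem cell genes changed in part. The formative list rose through Otx2 (1.53, adjusted p = 2.2e-05), Lef1 (1.04) and Dnmt3b (0.77) out of 11 genes, 4 adjusted over the list alone (adjusted p = 0.018; adjusted p = 0.437 with an estimated correlation). Of 26 pluripotency genes 7 rose, such as Prdm14 (0.62) and Dppa2 (0.68), 3 fell, such as Tbx3 (-0.58) and Tcl1 (-0.62), and 16 did not pass, with 9 rises and 3 falls adjusted over the list alone (adjusted p = 0.0193; adjusted p = 0.485 with an estimated correlation). Of the 12 cholesterol synthesis genes 4 rose, such as Fdps (0.48) and Nsdhl (0.47), and 6 adjusted over the list alone (adjusted p = 0.00233). Of the 16 glycolysis and hypoxia genes 3 rose, such as Egln3 (0.77) and Ndrg1 (0.63), and 1 fell, with 5 rises and 1 fall adjusted over the list alone (adjusted p = 0.0237). Of the 4 reprogramming factors Myc rose, 2 adjusted over the list alone (adjusted p = 0.0456). The last 3 lists each had adjusted p = 0.437 with an estimated correlation and, with the pluripotency list, lost their calls under quantile normalization. Without dim probe sets the formative, pluripotency, glycolysis and reprogramming factor lists lost theirs, the last also with array medians centred. Without fibroblast-derived array 2 the pluripotency, formative and reprogramming factor lists lost theirs as well (0.0668, 0.115 and up to 0.154), as did the reprogramming factor list without 5 other arrays and the glycolysis list without fibroblast-derived array 1 or 3 (0.0742 and 0.0892). The germline list was not called (adjusted p = 0.355), with 4 of 15 genes higher and 2 lower, such as Dazl (0.76) and Mael (0.49) among the first and Mov10l1 (-0.68) among the second, at adjusted p of 0.00175 to 0.00298.

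**Figure D2:**
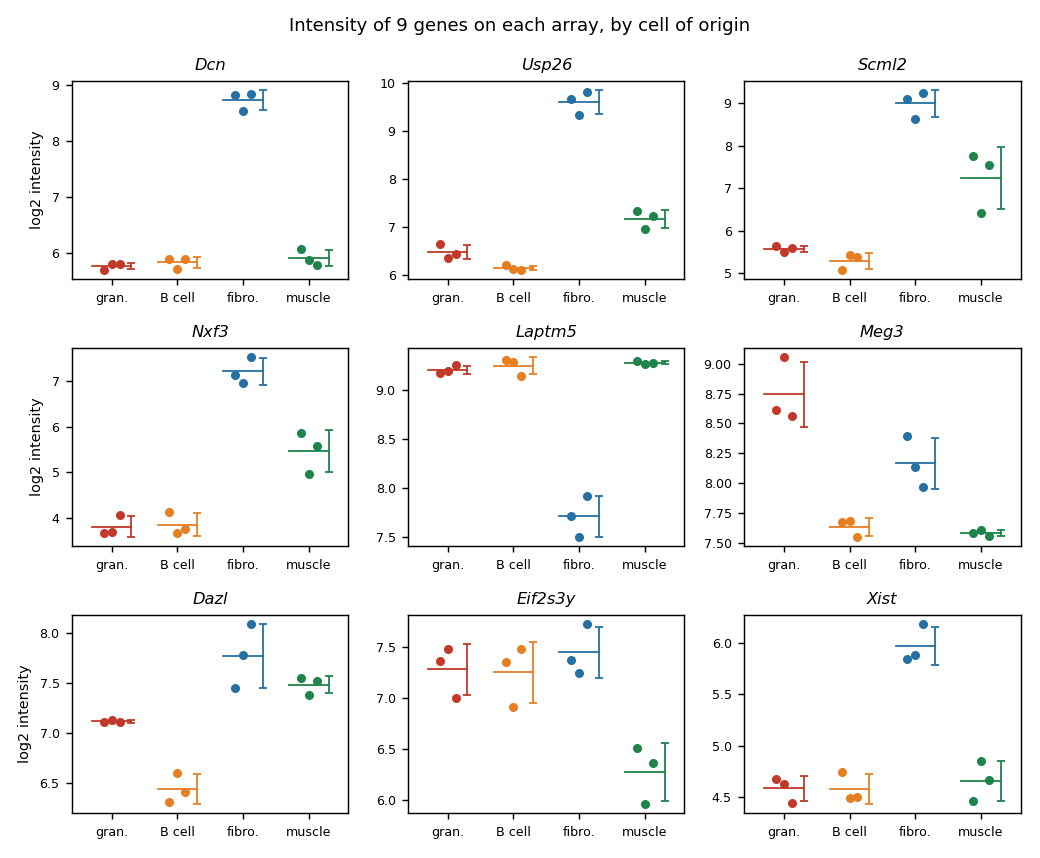
Log2 intensity of 9 genes on the 12 arrays, grouped by cell of origin. Points are the 3 arrays of an origin, the line is their mean and the bar their SD, and Dcn lies at 8.74 in fibroblast-derived arrays and at 5.76 to 5.90 in the other origins.

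A large part of the higher calls of fibroblast-derived cells lay on chromosome 11. Of its 1563 genes 483 were higher, or 30.9%, against 6.66% elsewhere (Fisher's exact test, adjusted p = 2.31e-157), and they made up 28.4% of the genes that rose. Irgm1 is among them. Over expressed genes and relative to the blood origins, chromosome 11 lay above the genome by 0.263, 0.289 and 0.253 on the log2 scale in the 3 fibroblast-derived arrays, and by 0.064, 0.004 and 0.057 in the muscle precursor-derived arrays. Of 14 blocks of neighbouring genes 12 were shifted by over 0.1 in all 3 fibroblast-derived arrays, against 0 of 141 blocks elsewhere. In all 3 muscle precursor-derived arrays 2 of the 14 were so shifted (lowest shifts 0.122 and 0.18), against 13 of 141 blocks elsewhere. Of the 19 matrix genes that rose, 18 lie on other chromosomes.

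**Figure D3:**
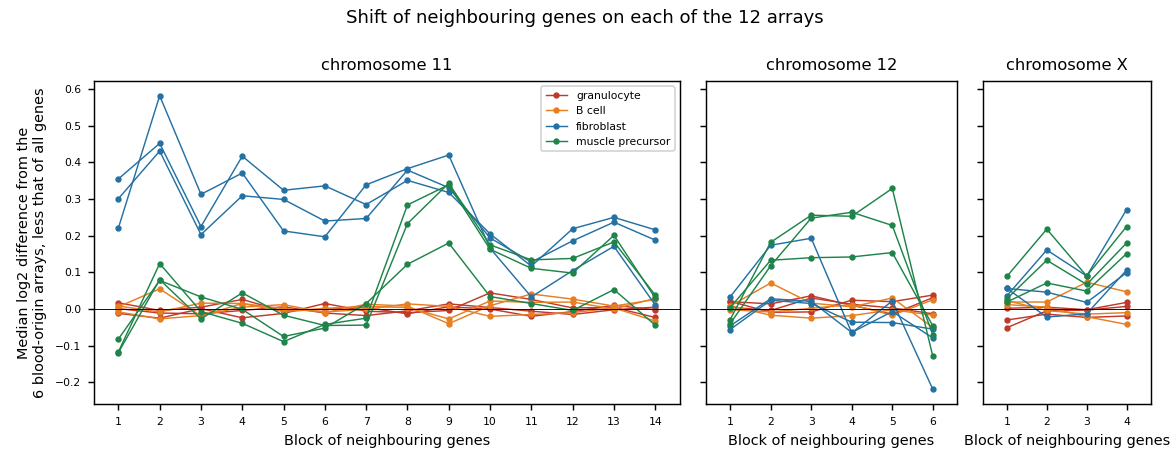
Median shift of blocks of 60 neighbouring expressed genes along chromosomes 11, 12 and X in each array, in log2 units against the 6 blood-origin arrays and less the shift of all genes. On chromosome 11 all 14 blocks lie above 0 in the 3 fibroblast-derived arrays, the lowest at 0.011.

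In all, 2364 probe sets were higher and 1577 lower in fibroblast-derived cells (3941 calls, 2746 genes), and 169 differed at least 2-fold, 136 higher and 33 lower. The higher share was 60%, and 74.5% with array medians centred. Calls numbered 7458, 2439 and 2621 without fibroblast-derived array 1, 2 or 3, and 3054 when the genes of chromosome 11 were left out, a fit chosen after seeing the data.

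Muscle precursor-derived cells against the other 3 origins asks what sets these cells apart. The predicted gene Gm5662 was 4.09-fold higher (log2 difference 2.03, SE 0.241, limma with Benjamini-Hochberg adjustment, adjusted p = 0.00678, 3 arrays against 9), followed by Gm7982 (2.16-fold, adjusted p = 0.00678) and the Y-linked Srsy (2.01-fold, adjusted p = 0.0149). In B cell-derived cells Gm5662 lay below the lower quartile of the arrays, so that its fold depends in part on the background. The nuclear gene Sp140, the X-linked Chic1, the microRNA precursor Mir680-2, the mediator subunit Med6, the chaperone subunit Pfdn4, Tmem92 and the ataxin gene Atxn3 rose by 0.78 to 0.83, with adjusted p of 0.00678 to 0.0233. Lower were Gm10548 (2.11-fold, adjusted p = 0.00849), the Y-linked Eif2s3y (2.07-fold, adjusted p = 0.00981) and Uty (-0.69, adjusted p = 0.0192), Gm10139 (-0.70), the chemoattractant gene Rarres2 (-0.65), the matrix proteoglycan biglycan (Bgn, -0.64), Vwa3b (-0.63), the oocyte gene Nlrp4a (-0.61), the nucleic acid sensor Zbp1 (-0.60) and smooth muscle actin (Acta2, -0.58). A second probe set of Gm10548 differed by -0.24 (adjusted p = 0.27), and 1 of the 8 probe sets of Vwa3b was called. Gm5662, Gm7982, Med6, Atxn3, Gm10548, Gm10139 and Bgn kept their calls with each array left out. Sp140 and Eif2s3y lost theirs without muscle precursor-derived array 3 (0.0597 and 0.0501), Rarres2 and Acta2 without array 1 (0.0537 and 0.0652), and Chic1, Mir680-2, Pfdn4, Tmem92, Uty, Vwa3b and Zbp1 without array 1 or 3 (0.0507 to 0.103). Srsy and Nlrp4a lost theirs without any of the 3, and Nlrp4a without B cell-derived array 1 (0.0505 to 0.127).

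In muscle precursor-derived cells the matrix list was lower and the germline list higher. Of 28 matrix genes 0 rose, 11 fell and 17 did not pass, with 18 falls adjusted over the list alone and a median of -0.31, such as Dcn (-0.87), Thbs2 (-0.57) and Col6a3 (-0.49; camera, adjusted p = 1.68e-09, and adjusted p = 0.092 with an estimated correlation). The Dcn difference comes from the fibroblast-derived arrays, as its mean was 5.90 here and 5.76 and 5.83 in the blood origins, while Thbs2 (6.35) and Col6a3 (6.18) were lowest here of all 4 origins. Of 15 germline genes 4 rose and 11 did not pass, with 8 rises adjusted over the list alone (adjusted p = 0.000135; adjusted p = 0.296 with an estimated correlation). Sycp3 (0.62), Ddx4 (0.53), Stk31 (0.48) and Asz1 (0.47) had adjusted p of 0.0286 to 0.0444, up to 0.19 with 1 array left out. Of 5 Y-linked genes 4 fell by either adjustment, with Kdm5d at -0.51 and Zfy1 at -0.68, and Usp9y did not pass (adjusted p = 0.000249; adjusted p = 0.0834 with an estimated correlation). Kdm5d (3.74) and Zfy1 lay below the lower quartile of the muscle precursor-derived arrays, so that their differences depend on the background. The Zfy1 difference comes largely from fibroblast-derived cells (mean 5.06), as its mean was 3.54 here, near that of B cell-derived cells, and 4.00 in granulocyte-derived cells. Kdm5d lost its call without muscle precursor-derived array 1 or 3 and Zfy1 without 8 of the arrays (0.056 to 0.137). The formative list fell through Otx2 (-0.77, adjusted p = 0.0084) and Fgf5 (-0.49) out of 11 genes, 4 adjusted over the list alone (adjusted p = 0.00659; adjusted p = 0.369 with an estimated correlation). The interferon response list fell through Oasl2 (-0.51) and Ifit1 (-0.48) out of 11 genes, 3 adjusted over the list alone (adjusted p = 0.00596; adjusted p = 0.133 with an estimated correlation). The Oasl2 difference comes largely from the fibroblast-derived arrays in the comparison group, in which this gene rose. The interferon call was lost without dim probe sets. Without muscle precursor-derived array 1 or 3 Fgf5, Oasl2 and Ifit1 lost their calls, and Fgf5 and Ifit1 lost theirs without others too (up to 0.15). The skeletal muscle precursor list was not called (adjusted p = 0.076). Of its 30 genes 1 rose, 3 fell, such as the troponins Tnnt1 (-0.36) and Tnnt3 (-0.42), and 26 did not pass, and with 1 array left out the adjusted p of both troponins reached 0.0808 and 0.115.

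A further 6 lists were called in muscle precursor-derived cells. Of 26 pluripotency genes 7 rose, such as Tcl1 (0.54, adjusted p = 0.00696), with 11 rises and 2 falls adjusted over the list alone (adjusted p = 0.00651; adjusted p = 0.464 with an estimated correlation). Of 12 cholesterol synthesis genes 4 rose, such as Msmo1 (0.49), and 6 adjusted over the list alone (adjusted p = 0.00391), and of 19 oxidative phosphorylation genes 3 rose, such as Ndufa9 (0.39), with 4 rises and 1 fall adjusted over the list alone (adjusted p = 0.0193). In the ribosomal list Rpl5 (0.29) was the 1 rise of 15 by either adjustment (adjusted p = 0.0334). In the pan-blood list Laptm5, low in fibroblast-derived cells alone, rose (0.56) and Cd53 fell (-0.42) out of 19 by either adjustment, while the list fell (adjusted p = 0.0263). These 4 lists had adjusted p = 0.437 with an estimated correlation. In the mitotic list Cdk1 (0.47) was the 1 rise of 14 by either adjustment (adjusted p = 0.00925; adjusted p = 0.471 with an estimated correlation). All 6 list calls were lost under quantile normalization and without dim probe sets, the pan-blood and ribosomal calls also without chromosome 11 genes (chosen after seeing the data), and the mitotic call with fry. Lost without 1 array were the pan-blood, ribosomal and pluripotency calls, without muscle precursor-derived array 2, 1 and 3 in that order (0.0617, 0.109 and 0.0571). Of the genes named here Tcl1 kept its call with each array left out, and the others reached an adjusted p of 0.0512 to 0.148. Meg3 and Rian of the Dlk1-Dio3 cluster were lower in these cells (-0.60 and -0.51, adjusted p = 0.0163 and 0.0216) than the mean of the other 3 origins, but for Meg3 near B cell-derived cells (7.58 and 7.64), and each lost its call without any 1 of the 3 muscle precursor-derived arrays (0.0507 to 0.096). Rian (4.08 here and 4.29 in B cell-derived cells) lay below the lower quartile of those arrays, so that its difference depends on the background.

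**Figure D4:**
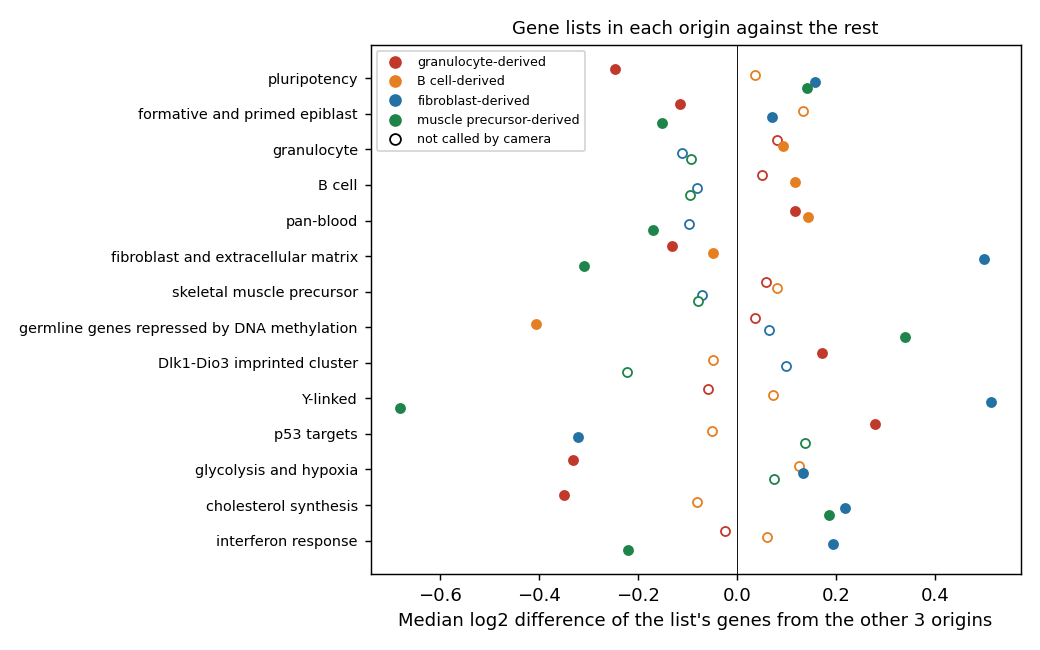
Median log2 difference of 14 gene lists in the contrast of each origin with the other 3. Filled points were called by camera with a preset correlation, and the matrix list lies at 0.50 in fibroblast-derived and -0.31 in muscle precursor-derived cells.

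In all, 1842 probe sets were higher and 876 lower in muscle precursor-derived cells (2718 calls, 1498 genes), and 149 differed at least 2-fold, 131 higher and 18 lower, of which 86 have no gene name. The higher share was 67.8%, 55.7% under quantile normalization and 78.4% with array medians centred. Of the 652 genes of chromosome 12, 120 were higher, or 18.4%, against 4.59% elsewhere (Fisher's exact test, adjusted p = 2.39e-34), and Gm5662, Med6 and Atxn3 are on it. Over expressed genes and relative to the blood origins, chromosome 12 lay above the genome by 0.136, 0.084 and 0.154 in the 3 arrays, with 4 of 6 blocks shifted by over 0.1, against 9 of 135 blocks outside chromosomes 11 and 12. The X lay above it by similar amounts (0.108, 0.087 and 0.156), with 1 of 4 blocks so shifted. Chromosomes 3 and 13 were shifted by 0.054 to 0.107, while others, such as chromosome 7 (-0.078 to -0.107), lay below the genome. The count of calls was 139, 786 and 148 without muscle precursor-derived array 1, 2 or 3, 1456, 1264 and 1658 without granulocyte-derived array 1, 2 or 3, 1309 and 1293 without B cell-derived array 1 or 2, and 6130 without fibroblast-derived array 3.

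Blood against non-blood origins asks whether 2 haematopoietic origins share a profile. A set of X-linked genes was lower in the 6 blood-origin arrays: Scml2 (6.45-fold, log2 difference -2.69, SE 0.204, limma with Benjamini-Hochberg adjustment, adjusted p = 5.95e-05), Nxf3 (SE 0.162, adjusted p = 2.16e-05, below the lower quartile of the blood-origin arrays), Usp26 (4.19-fold, SE 0.0953, adjusted p = 4.11e-06), Efhc2 (3.65-fold, adjusted p = 1.73e-05) and the nucleosome-binding gene Hmgn5 (2.58-fold, adjusted p = 0.00052). Higher were Macrod2 (2.55-fold, adjusted p = 0.00196), the hepcidin gene Hamp2 (2.10-fold, adjusted p = 0.00126), Cfap43 (adjusted p = 0.0066), the synaptic scaffold gene Shank2 (2.02-fold, adjusted p = 0.00207) and the microRNA precursor Mir346 (2.01-fold, adjusted p = 0.00168). All 10 kept their calls in every setting run for them. The other probe sets of Macrod2 (6 in total) differed by -0.12 to 0.33 and those of Shank2 by 0.15 and 0.17. Of these only the Macrod2 probe set at 0.33 was called (limma, adjusted p = 0.0086), so that both results rest largely on 1 probe set. The other probe sets of Cfap43 differed by 0.24 to 0.48. Myc and Xist were called lower (-0.41 and -0.73, adjusted p = 0.00336 and 0.000753), but muscle precursor-derived cells (6.34 and 4.66) lay near the blood origins and the fibroblast-derived cells alone were high (7.01 and 5.97). Meg3 and Rian were called higher (0.32 and 0.29, adjusted p = 0.0314 and 0.0338) through granulocyte-derived cells alone, since B cell-derived cells (4.29 for Rian) lay below fibroblast-derived cells for both, and each lost its call without 8 of the arrays in turn (up to 0.0739) and with array medians centred. The Rian means of B cell-derived and muscle precursor-derived cells lay below the lower quartile of their arrays.

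Blood-cell lists rose slightly in blood-origin cells and several stem cell and metabolic lists fell. In the deposited values the blood-origin arrays had the narrower spread of intensities. Under quantile normalization, which gives all arrays the same spread, the pan-blood, granulocyte, B cell and pluripotency calls were lost. Of 19 pan-blood genes 5 rose, such as Laptm5 (0.73, adjusted p = 0.000247), Selplg (0.51) and Itgb2 (0.33), of 28 granulocyte genes 6 rose, such as Ncf1 (0.38) and Ngp (0.37), and 1, Anxa1, fell (-0.87), and of 23 B cell genes 4 rose, such as Cd37 (0.36) and Ighm (0.45). These counts were the same adjusted over the list alone. The lists had an adjusted p of 0.018, 0.0284 and 0.0312, and adjusted p = 0.437 with an estimated correlation for the first and second and 0.485 for the third. Laptm5 was as high in muscle precursor-derived cells (mean 9.28) as in the blood origins. Of 12 cholesterol synthesis genes 8 fell, such as Nsdhl (-0.51) and Sqle (-0.44), and 11 adjusted over the list alone (adjusted p = 2.86e-05; adjusted p = 0.368 with an estimated correlation). Of 26 pluripotency genes 11 fell and 1 rose, such as Dppa3 (-1.06, adjusted p = 0.000768), Fbxo15 (-0.74) and Dppa2 (-0.59), with 15 falls and 2 rises adjusted over the list alone (adjusted p = 0.00124; adjusted p = 0.437 with an estimated correlation). Of 28 matrix genes 13 fell and 1 rose by either adjustment, such as Mfap5 (-0.61) and Lum (-0.50; adjusted p = 0.00391, and adjusted p = 0.421 with an estimated correlation). Against the other origins the matrix list was higher in fibroblast-derived but lower in muscle precursor-derived cells. As a list, its fall in blood origins thus comes mainly from the fibroblast-derived arrays. Of 15 germline genes 6 fell, such as Dazl (-0.85), Asz1 (-0.82) and Mael (-0.44), with 7 falls and 1 rise adjusted over the list alone (adjusted p = 0.00922; adjusted p = 0.437 with an estimated correlation). Of 15 p53 targets 7 rose, such as Phlda3 (0.56) and Perp (0.54), and 1 fell, with 9 rises and 1 fall adjusted over the list alone (adjusted p = 0.00925; adjusted p = 0.368 with an estimated correlation). Of the single origins, the p53 list was called in granulocyte-derived and fibroblast-derived cells alone. The difference is thus not shown to be shared by B cell-derived or muscle precursor-derived cells. Without dim probe sets the pluripotency, matrix and germline calls were lost.

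Further lists were called for blood origins with an adjusted p of 0.0145 to 0.0379. The glycolysis and hypoxia list (5 of 16 fell by either adjustment, such as Ndrg1 at -0.53), the mitotic list (5 of 14 fell by either adjustment, such as Top2a at -0.37) and the oxidative phosphorylation list (7 of 19 fell by either adjustment, such as Ndufv1 at -0.49) were lower. Of the single origins, the glycolysis list was called in granulocyte-derived and fibroblast-derived cells alone. The keratinocyte list (3 of 10 rose, 7 adjusted over the list alone, such as Ivl at 0.49) and the primitive streak list (6 of 11 rose by either adjustment, such as Lhx1 at 0.49 and Msgn1 at 0.33) were higher. Of these the mitotic list had adjusted p = 0.485 with an estimated correlation and the other 4 had adjusted p = 0.437 with an estimated correlation. Under quantile normalization the calls of the pan-blood, granulocyte, B cell, pluripotency, keratinocyte, streak, mitotic, glycolysis and oxidative phosphorylation lists were lost, and the median of the last turned from -0.10 to 0.05 (adjusted p = 0.98). Without dim probe sets those of the keratinocyte, streak, mitotic, glycolysis and oxidative phosphorylation lists were lost. Without fibroblast-derived array 3 the granulocyte, B cell, streak and mitotic lists lost theirs (0.0545 to 0.0679), the streak list also without muscle precursor-derived array 2, and the oxidative phosphorylation list lost its own without granulocyte-derived array 1 (0.0606). The streak and mitotic calls were also lost without chromosome 11 genes, a fit chosen after seeing the data.

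Blood origins gave 10266 calls (4815 higher, 5451 lower, 6202 genes), with 81 higher and 216 lower by at least 2-fold, of which 214 have no gene name. The higher share was 46.9%, and 27.9% with array medians centred. Of chromosome 11 genes 33.7% fell, against 15.1% elsewhere, and the shift of this chromosome lies mostly in the fibroblast-derived arrays (0.253 to 0.289, against 0.004 to 0.064 in the muscle precursor-derived arrays). Leaving out 1 array moved this count by less than 1.5-fold.

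Of the 160 list tests, 54 were called by camera, 0 with an estimated correlation and 76 by fry. Of 100 groupings of the arrays into 4 sets of 3, the other 99 gave up to 45 calls with a median of 25, so that a call of a list in this data set is weak by itself. The lists without a call in any of the 5 contrasts had lowest adjusted p of 0.0504 (immediate early genes), 0.0642 (posterior Hox genes), 0.0682 (neuroectoderm), 0.076 (skeletal muscle precursor), 0.0956 (macrophage), 0.1 (erythroid), 0.101 (imprinted genes outside the Dlk1-Dio3 cluster), 0.133 (T cell), 0.22 (trophoblast) and 0.254 (endothelial).

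The pairwise contrasts show where the differences lie. No single probe set was called between granulocyte-derived and B cell-derived cells: limma called 0 of 35556, with 2723 at an unadjusted p under 0.05, although each of these 6 arrays was nearest to 1 of its own origin. The count was 1 when these 6 arrays were fitted alone, 1 under quantile normalization, 3 with a trended robust prior, 24 without dim probe sets, 30 with probe sets of 1 symbol, 170 with array quality weights, 6 without fibroblast-derived array 3 and 2 without muscle precursor-derived array 3.

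Against fibroblast-derived cells both blood origins were lower in Dcn, Usp26, Scml2, Nxf3 and Efhc2 and higher in Laptm5. For Nxf3, at 3.81 and 3.85 in the blood origins and 7.22 in fibroblast-derived cells, no fold is given, as the lower values lie below the lower quartile of their arrays. In granulocyte-derived cells Scml2 was 10.8-fold lower, Usp26 8.65-fold, Dcn 7.85-fold (SE 0.107, adjusted p = 3.57e-07) and Efhc2 4.36-fold, while Laptm5 (2.82-fold, adjusted p = 1.77e-05), Efna3 (2.73-fold), Cfap43 (2.85-fold), Tns1 (1.56) and Usp17ld (7.34-fold, SE 0.694, adjusted p = 0.0185) were higher. Usp17ld lost its call without fibroblast-derived array 2 or 3 (0.0646 and 0.0671), as did Tns1 without these or granulocyte-derived array 1 (0.084 to 0.0936), and both lost theirs under array quality weights. Of the 6 probe sets of Tns1 the others differed by 0.51 or less. In B cell-derived cells Scml2 was 13.1-fold lower, Usp26 10.9-fold, Dcn 7.52-fold (SE 0.107, adjusted p = 4.5e-07) and Efhc2 5.27-fold, while Laptm5 (2.90-fold), Pdgfc (2.31-fold, adjusted p = 0.000267), Adssl1 (1.09), Btnl5-ps (1.28) and Macrod2 (1.25) were higher. Btnl5-ps and Macrod2 lost their calls without 9 and 5 of the arrays in turn (up to 0.135), Macrod2 also under array quality weights. Granulocyte-derived cells gave 5613 calls (2368 higher, 3245 lower) and B cell-derived cells 3967 (1570 higher, 2397 lower). The higher share was 42.2% and 39.6%, and 25.2% and 23.3% with array medians centred. The first count was 2631, 3258 and 3651 without granulocyte-derived array 1, 2 or 3 and 9106 and 3647 without fibroblast-derived array 1 or 3. The second was 1193, 1166 and 2216 without B cell-derived array 1, 2 or 3 and 8567, 2255 and 1517 without fibroblast-derived array 1, 2 or 3.

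Against muscle precursor-derived cells both blood origins were lower in Gm5662, Scml2 and Nxf3. In granulocyte-derived cells Gm5662 was 3.30-fold (SE 0.295, adjusted p = 0.011) and Scml2 3.18-fold lower, with Nxf3 at 3.81 against 5.46, Lsm5 (-1.44) and Arxes2 (-1.36), and Meg3 (2.24-fold, SE 0.137, adjusted p = 0.00402), Btnl5-ps (1.54), Macrod2 (1.45), Hamp2 (2.40-fold) and Gm15455 (1.24) were higher. Meg3 and Nxf3 kept their calls with each array left out. Gm5662, Scml2, Hamp2 and Arxes2 lost theirs without muscle precursor-derived array 3 (0.0504 to 0.0556) and the other 4 without 4 to 7 of the arrays in turn (up to 0.118). In B cell-derived cells Gm5662 was at 3.63 against 6.30 (SE 0.295, adjusted p = 0.00333) and Nxf3 at 3.85 against 5.46, the lower values again below the lower quartile, and Scml2 was 3.87-fold and Efhc2 3.06-fold lower, with Lsm5 at -1.53, and Btnl5-ps (3.19-fold), Macrod2 (1.34), Gm10548 (1.20), Mir346 (1.16) and Hamp2 (2.20-fold) were higher. Lsm5, Btnl5-ps, Macrod2, Mir346 and Hamp2 lost their calls without 4 to 6 of the arrays (up to 0.0986). Other probe sets of Macrod2 and Btnl5-ps differed less, and 1 of 3 probe sets of Lsm5 was not called. Granulocyte-derived cells gave 3574 calls (1261 higher, 2313 lower) and B cell-derived cells 3848 (1388 higher, 2460 lower). The higher share was 35.3% and 36.1%, 47.4% and 47.5% under quantile normalization, and 20% and 22.2% with array medians centred. The first count was 420, 633 and 1282 without granulocyte-derived array 1, 2 or 3, 1297, 1801 and 274 without muscle precursor-derived array 1, 2 or 3, and 5710 and 5402 without fibroblast-derived array 1 or 3. The second was 195, 356 and 1886 without B cell-derived array 1, 2 or 3, 540, 1734 and 514 without muscle precursor-derived array 1, 2 or 3, and 6136 and 6190 without fibroblast-derived array 1 or 3.

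Between the non-blood origins, fibroblast-derived cells were higher in Dcn (7.12-fold, SE 0.107, adjusted p = 6.12e-07), Usp26 (5.37-fold, adjusted p = 2.16e-05), Ddx60 (6.01 against 4.13, the latter below the lower quartile of its arrays, adjusted p = 4.78e-05), Irgm1 (3.47-fold) and Scml2 (3.39-fold), and lower in Gm5662 (3.26-fold, adjusted p = 0.00868), Laptm5 (2.97-fold, adjusted p = 4.16e-05), Gm7982 (2.64-fold), Adssl1 (2.38-fold) and Tgm1 (2.19-fold, adjusted p = 3.32e-05). All 10 kept their calls in every setting run for them. This contrast gave 1616 calls (841 higher, 775 lower), 157 of them of at least 2-fold. The count was 667, 836 and 927 without muscle precursor-derived array 1, 2 or 3 and 2777 without fibroblast-derived array 3.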

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

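With 3 arrays per origin the counts of calls depend on the settings far more than the directions do. Of 130 counts and similarity values under other settings 88 stayed the same and 42 moved. A count stayed the same if within 1.5 times the reported value. The similarity stayed the same if it kept its sign and a permutation p under 0.05. Of 5408 values of named genes 4922 kept their side of the threshold, 134 lost it, 352 gained it and 0 reversed. Of 480 values of called lists 352 kept their call, 127 lost it and 1 reversed. Probe sets near background show little of a difference in their transcripts, so that a missing call among dim genes says little. With a group reduced to 2 arrays, its spread is pooled with that of the other groups. Except where the construction of a setting shows it, the cause was not tested.

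Calls of at least 2-fold, which are fewer by construction, numbered 870 (F test), 46 (granulocyte), 27 (B cell), 169 (fibroblast), 149 (muscle precursor), 297 (blood), 418 (granulocyte against fibroblast), 253 (granulocyte against muscle precursor), 346 (B cell against fibroblast), 469 (B cell against muscle precursor) and 157 (fibroblast against muscle precursor). Quantile normalization gave 261 for B cell, 1 for granulocyte against B cell and 28 list calls. It reversed 1 median, that of the oxidative phosphorylation list, blood origins against non-blood origins, to 0.0505 (adjusted p = 0.98). Centred medians gave 267 for B cell. Without dim probe sets there were 3497 for granulocyte, 1261 for B cell, 24 for granulocyte against B cell and 25 list calls. Probe sets with 1 symbol gave 1192 for B cell and 30 for granulocyte against B cell, and the trended robust prior gave 635 and 3. Without chromosome 11, a setting chosen after seeing the data, B cell had 79. Camera with an estimated correlation called 0 lists.

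Array quality weights turned the order of the origins over, with the fewest calls for fibroblast, and gave 4676 (granulocyte), 4059 (B cell), 1548 (fibroblast), 4658 (muscle precursor), 170 (granulocyte against B cell), 3719 (granulocyte against fibroblast), 7438 (granulocyte against muscle precursor), 2308 (B cell against fibroblast), 8759 (B cell against muscle precursor) and 835 (fibroblast against muscle precursor). Fitted on their own 6 arrays, the contrasts of 1 origin with another gave, in the order of the last 6, 1, 1770, 5905, 547, 6392 and 165. The replicate block gave 274 for B cell and changed no other count by over 1.5 times. Of the list calls it ended that of the primitive endoderm list, B cell-derived against the other origins (adjusted p = 0.0584), and of the genes named by rank that of Cacng1 in the same contrast. Of 18 pairs of arrays with the same number and different origins 3 correlated above 0.1. The mean was 0.0498, against -0.0249 for pairs with different numbers, and 8 of 12 arrays were best matched by their own number, a hint from the data that the numbers share something. The labels name no shared source, and the numbers were not treated as pairs.

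With 1 array left out, counts ran from 4275 to 10262 (F test), 181 to 5154 (granulocyte), 16 to 4299 (B cell), 2439 to 7458 (fibroblast), 139 to 6130 (muscle precursor), 7324 to 13191 (blood), 0 to 6 (granulocyte against B cell), 2631 to 9106 (granulocyte against fibroblast), 274 to 5710 (granulocyte against muscle precursor), 1166 to 8567 (B cell against fibroblast), 195 to 6190 (B cell against muscle precursor) and 667 to 2777 (fibroblast against muscle precursor), with 48 to 60 list calls and a similarity difference of 0.439 to 0.543 (p at most 0.0002597). Of 8496 values of named genes 7370 kept their side, 951 lost it, 175 gained it and 0 reversed, and of 648 values of called lists 603 kept their call and 45 lost it.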

Other observations

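The tests of chromosome 11, of the X-linked genes and of the matrix genes were chosen only after the results were seen, and so was the bound of 12 blocks for chromosome 11.

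Genes in this and the next paragraph were chosen after their values were seen. The precursors of the microRNA cluster of pluripotent cells were higher in fibroblast-derived cells: Mir302b rose by 1.35 (SE 0.159, adjusted p = 0.000426), Mir302c by 0.89 (adjusted p = 0.00161), Mir302a by 0.83 (adjusted p = 0.00161) and Mir302d by 0.71 (adjusted p = 0.00538), while Mir367 did not pass (0.36, adjusted p = 0.0654). In granulocyte-derived cells Mir302b and Mir302a fell (-0.90 and -0.51, adjusted p = 0.0124 and 0.0366), and Mir302c and Mir302d did not pass (adjusted p = 0.0566 and 0.101). Without granulocyte-derived array 1 or 2 Mir302b lost its call (up to 0.0724), as did Mir302a without 7 of the arrays (up to 0.152). The simple epithelial keratin Krt8 fell by 0.96 in fibroblast-derived cells (SE 0.0937, adjusted p = 0.000129) and rose by 0.68 in granulocyte-derived cells (adjusted p = 0.00461).

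Imprinted genes outside the Dlk1-Dio3 cluster moved both ways. In fibroblast-derived cells 6 of 23 rose, among them Mest (0.84, adjusted p = 0.00821), Peg3 (0.66, adjusted p = 0.00487) and Ndn (0.62, adjusted p = 0.00293), and 3 fell, with 6 and 4 adjusted over the list alone. Igf2 was lower in fibroblast-derived and in muscle precursor-derived cells (-0.58 and -0.57, adjusted p = 0.000932 and 0.00704). Among genes of the early embryo, Pdgfra (1.32, adjusted p = 5.58e-05) and Tubb3 (0.68, adjusted p = 0.00678) rose and Gata4 (-0.64, adjusted p = 0.000122) fell in fibroblast-derived cells. The growth factor target Ccn2 fell (-0.72, adjusted p = 9.42e-05) and Egr1 rose (0.41, adjusted p = 0.00832).

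The excess of chromosome 11 transcripts in fibroblast-derived cells could come from a trend with intensity or gene length, from scaling, or from more copies of the chromosome. The median log2 difference of chromosome 11 genes was 0.2841, against 0.023 for the other genes. In 10000 random gene sets matched on intensity and gene length it was at most 0.0498. With the trend removed, the excess over the other genes was 0.265. After quantile normalization the median was 0.2247, against -0.0273 for the other genes and at most 2e-04 in matched sets. The excess with the trend removed was then 0.2586. These values argue against both technical explanations. Blocks of neighbours shifted by over 0.1 in all 3 arrays numbered 12 of 14 on chromosome 11 and 0 of 141 elsewhere, in line with more copies of the chromosome in these cells. In all 3 muscle precursor-derived arrays 2 of the 14 blocks were shifted, against 13 of 141 elsewhere, so that chromosome 11 does not stand out in these arrays. Expression alone does not count copies, and a DNA measurement of the same cells would decide.

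The 5 X-linked genes with the largest excess in non-blood origins might reflect more output of the whole X chromosome or a loss of repression of germline genes. The median of 287 X-linked genes was higher by 0.188, with an interquartile range of 0.343, while the smallest difference of the 5 was 1.37. An even shift of all X-linked genes by that median is smaller than these differences. The 5 were picked for their size, so that they lie above the median by construction, and the comparison cannot decide on the first explanation. A smaller excess covered many X-linked genes: 128 passed as higher in non-blood origins and 16 as lower, counts not set against the other expressed genes. Relative to all expressed genes, the X was shifted by 0.041 to 0.17 in the non-blood arrays. In the muscle precursor-derived arrays chromosomes 12 (0.084 to 0.154) and 13 (0.065 to 0.107) were shifted too, so that there the excess is not particular to the X. For the second the test cannot tell: the germline list was lower in blood origins with the preset correlation (adjusted p = 0.00922) and without a call with the estimated one (adjusted p = 0.437).

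The excess of matrix transcripts in fibroblast-derived cells could come from feeder or other fibroblasts carried over, from chromosome 11, or from the fibroblast origin itself. Of the 3 abundant matrix transcripts 2 (Vim and Col1a1) were higher and Fn1 was lower, which leaves carry-over undecided. Col1a1 lies on chromosome 11, which is itself shifted upward in these arrays. Of the 19 members that rose 18 lie on other chromosomes, so a shift of the genes on chromosome 11 does not account for these 18. Effects of chromosome 11 on genes elsewhere were not tested. A retained trace of the origin was not tested apart from carry-over. Nor can it be told apart from a difference between clones, as the labels do not say whether the replicates are separate clones.

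Each count was set against other splits of the arrays, with the real split included in the number as large. Of 100 splits, 1 was as large for the F test (7122, highest other 393), for granulocyte (2100, highest other 1614), for fibroblast (3941, highest other 1497), for muscle precursor (2718, highest other 1362) and for blood origins (10266, highest other 1491), and 1 for the list calls (54, highest other 45). That share is under 5% for these 6. The splits for 1 origin and for blood origins also mixed arrays of distinct origins within each set of 3. This widens the residual spread and lowers the other counts, so these splits cannot exclude chance for 1 origin or for blood origins. For B cell 2 of 100 were as large (158, highest other 1824, from fibroblast-derived array 3 with muscle precursor-derived arrays 1 and 3). That is under 5%, but the larger count comes from 3 non-blood arrays and may reflect the difference of blood and non-blood origins (10266 calls), which was not tested. For granulocyte and for muscle precursor the highest other split was that of the 3 fibroblast-derived arrays. A pair of origins has 10 splits, too few to exclude chance: 10 of 10 were as large for granulocyte against B cell (0, highest other 0), and 1 for granulocyte against fibroblast (5613, highest other 1), granulocyte against muscle precursor (3574, highest other 0), B cell against fibroblast (3967, highest other 1), B cell against muscle precursor (3848, highest other 0) and fibroblast against muscle precursor (1616, highest other 1).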
